A study of Homo sapiens with 2 samples.

How the data were processed

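Expression was measured in 2 libraries of BxPC3 cells, 1 given a gold nanoparticle for 48 h and 1 untreated, grouped by the treatment given in the labels. Per the labels' protocols, libraries were built from 10 ng of total RNA with the Ampliseq Transcriptome kit, which amplifies targeted stretches of transcripts by PCR. The labels name a column kit for RNA isolation in one place and a phenol reagent in another, and which was used is unsure. Nothing in the labels says that further cultures were made. The only file analysed here is the authors' own comparison of the 2 libraries. Per the submitters' processing notes the hg19 build and DESeq were used. The aligner, the counting, the annotation, the scaling between libraries and the role DESeq had are not given in the sources used here.

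The deposited table gives 3 measures for each gene, checked against each other. The signed fold and the absolute fold are linear ratios of treated over untreated, as deposited by the authors, with a minus sign where the treated library is lower. The log2 fold deposited by the authors is the log2 of that ratio. All 8316 rows are at 2-fold or more, so the authors' file was filtered on size of change. No count, expression level or p-value was analysed here, so library depth is unknown. Reads copied by PCR are not independent molecules. The intervals given for shares of genes take genes as independent draws and hold no error of read counting. Genes of the same family may not be independent.

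The plan made before the data were examined called for a minimum mean expression, pseudocounts and random lists matched on expression. None of these can be applied to folds alone. The authors' folds were therefore used as deposited, with no test, because 1 library per group gives no estimate of spread. The planned rule of size, 2-fold, is also the table's own limit. Each of 44 gene lists fixed beforehand, with 853 genes in all, was matched to the table by gene symbol, and 465 of these genes were listed. Where a symbol stood on more than 1 row, the row whose identifier carries that name was used. For the 38 lists with at least 5 listed members the median log2 fold was taken. Its percentile among 10000 random lists of the same size, drawn from all listed genes, is given for some of these lists. This describes these 2 libraries and is not a test across samples. Genes named in the text are the 15 highest and the 15 lowest of the table and up to 4 members of each list with the largest change. Some genes that the rule picks are not reported here. The few genes named outside that rule are marked as such. Groups taken from the table's gene ontology column were chosen after the table was seen.

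The folds repeat on a regular spacing. Its size was found separately for higher and lower genes as the spacing of the most frequent values, refined by least squares over multiples up to 60. A fold was called a whole step if it lay within 0.0005 of a whole multiple, which 0.1% would by chance. It was called a simple fraction if the fold in steps, times a whole number up to 6, lay that close to a whole number. By chance 0.38% would be steps or fractions. The call of whole steps was tested on simulated data for the treated over untreated comparison. Reads divided between genes were not simulated, so the call of simple fractions was not tested. Of 20000 simulated genes 8776 passed 2-fold, 100% of those made to lie on a step were recovered, and 0.782% of those called were wrong. The ratio of both step sizes, 3.23, was used to put the folds on a second scale.

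Gene types and coding exons came from GENCODE release 29, matched by Ensembl identifier for 8154 of 8316 rows. That annotation is on another build than hg19, so it was used for types and exon numbers, and chromosome positions are not given. The alternatives were a 3-fold threshold, recentring on the median of the listed genes, recentring by the ratio of the step sizes, leaving out genes whose fold is on a step or fraction, the mean in place of the median, random lists matched on whether a fold is a whole step, and list medians with unlisted members put at either end of the unlisted range. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.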

Results

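Gene expression was profiled in BxPC3, an established human pancreatic adenocarcinoma cell line of ductal origin, with and without a gold nanoparticle. The series holds 2 libraries, 1 from cells given the gold nanoparticle for 48 h and 1 from untreated cells. Each library was made from 10 ng of total RNA with a targeted transcriptome amplicon kit. The values are the authors' own folds, treated over untreated. Their deposited table lists 8316 genes, every one at 2-fold or more in either direction. It gives no read counts, expression levels or p-values, so the depth of the libraries is unknown. With 1 library per group no difference has a replicate check. "Higher" and "lower" therefore describe these 2 libraries, not the treatment in general, and a gene that is not listed was either under 2-fold or not measured.

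The question the design poses is how the gold nanoparticle changed the transcriptome of the cancer cells. Most listed genes were lower in the treated library as deposited, among them genes of protein synthesis, energy metabolism, the secretory pathway, the lysosome and inflammatory signalling. The median of the ribosomal protein list, however, was less lowered than those of most random lists of listed genes. Of 8316 genes in the authors' deposited table, 6435 (77.4%) were lower and 1881 (22.6%) were higher. The median fold was 4.65 among the lower genes and 3.89 among the higher ones in the deposited table, and 1167 lower and 235 higher genes reached 10-fold. The direction depended on the kind of gene. Of the 7220 listed protein-coding genes 80.4% were lower, against 61.6% of 281 long non-coding genes and 50.8% of 597 pseudogenes. The kit amplifies targeted transcripts, and how reads were assigned to non-coding and pseudogene identifiers is not given in the sources used here, so these shares are uncertain. The split also rests on how the libraries were scaled against each other. The median log2 fold of all listed genes was -1.86. The deposited folds fall on regular steps, 0.299 wide among higher and 0.965 wide among lower genes, whose ratio of 3.23 is 1.69 on the log2 scale. Of all listed genes 2550 (30.7%) had folds at whole multiples of these steps and 506 at simple fractions, within 0.0005 of a step. The size of such a fold is uncertain, since the lower of both values may have been raised to 1. Many genes named below for large changes in their lists are of this kind. Among them are CRELD2, DNAJB9, MSMO1, HSD17B7, LAMA3, EDN1, VCL, MCM7, LIG1, SLC29A1, MT1E, MT3, CRYAB, ME1 and BNIP3. When 1.69 was added to every log2 fold (the step-adjusted scale used below), 2189 genes stayed at least 2-fold lower and 1881 or more were 2-fold higher, since unlisted genes would join these. Among the listed genes past 2-fold 53.8% were then lower. If 1 step is what 1 read is worth, the step-adjusted scale compares read numbers without scaling for library depth. A deeper treated library that was scaled correctly would give the same unequal steps. The step-adjusted scale is therefore a second view of the folds and not a correction. List medians on that scale are over listed members alone, since an unlisted member was either under 2-fold as deposited or not measured. Where unlisted members were given any value under 2-fold, 4 of 38 list medians lay below 0 on that scale (lysosome, hypoxia, endoplasmic reticulum chaperones and glycolysis). Where this turns the sign of a step-adjusted median, the value is given below as that with unlisted members. Every unlisted member lies at 0.69 or above on that scale by design. A value given as 0.69 or more is therefore set by this choice and not by the listed genes. When the median of the listed genes was set to 0, 1853 were at least 2-fold lower, 49.6% of the listed genes past 2-fold. That recentring puts 4158 listed genes on each side of 0 by design, so its near-even split says nothing about the scaling.

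**Figure D1:**
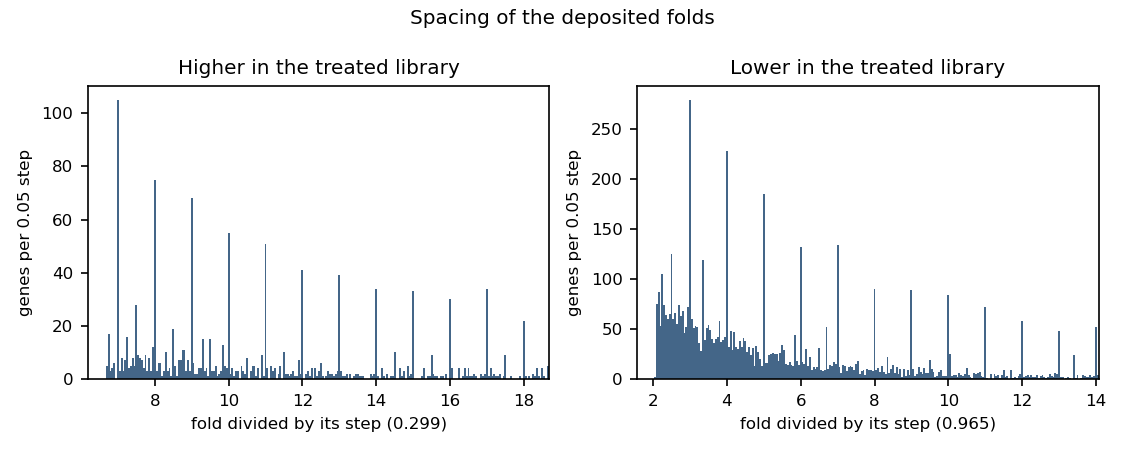
Number of genes (y axis, bins of 0.05 step) against the deposited fold divided by its step size (x axis, 0.299 for genes higher and 0.965 for genes lower in the treated library). The tall bars at whole numbers are the 932 higher and 1618 lower genes in the table whose folds are whole multiples of the step.

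**Figure D2:**
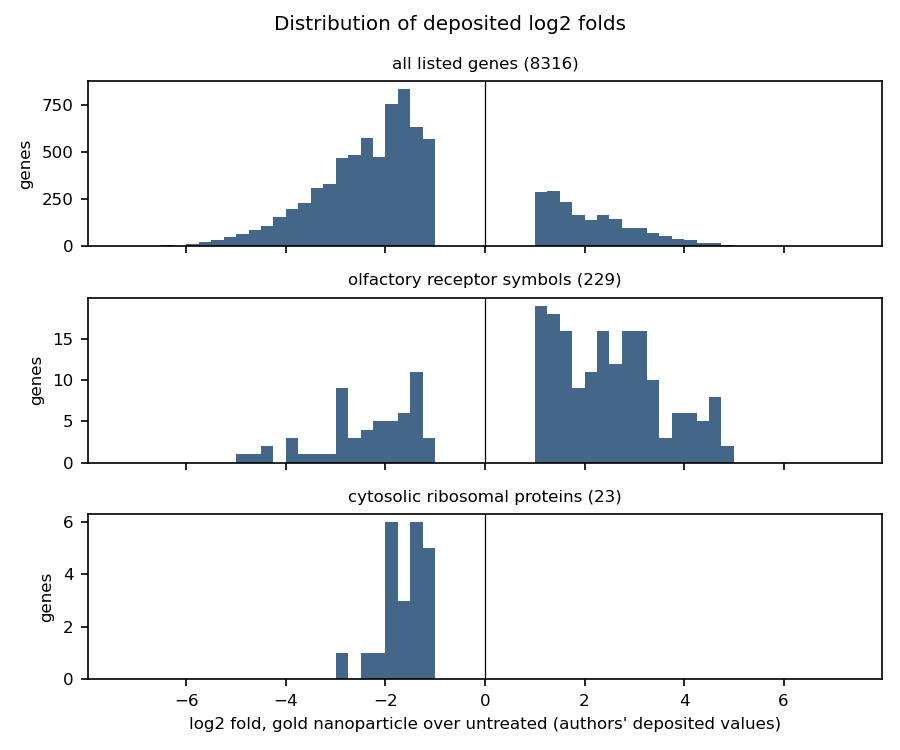
Histograms of the deposited log2 folds (x axis, gold nanoparticle over untreated, bins of 0.25) against the number of genes (y axis) for all 8316 listed genes, 229 genes with olfactory receptor symbols and 23 cytosolic ribosomal protein genes. Nothing is listed between -1 and 1, the ribosomal protein genes all lie below 0 (step-adjusted median 0.19), and 173 of the olfactory receptor genes lie above 0.

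The 15 lowest genes ranged from 73.4-fold to 131-fold lower in the authors' deposited table, and all were protein-coding. DAAM1 (ENSG00000100592), a formin that organises actin downstream of Wnt signalling, was 131-fold lower in the deposited table. DHX32 (ENSG00000089876), a putative RNA helicase, was listed at 117-fold lower in that deposited table. HBEGF (ENSG00000113070), an EGF receptor ligand, was 116-fold lower and IMPAD1 (ENSG00000104331) 111-fold lower in the deposited table. The deposited table also placed here KLHDC2 at 100.4-fold, RASD1 at 98.3-fold, the calponin CNN3 at 96.5-fold and the mRNA 3' end processing factor SYMPK at 95.1-fold lower. NCSTN, a subunit of gamma-secretase, and TIMP3, an inhibitor of matrix metalloproteinases, were both 85.9-fold lower in the deposited table. The remaining 5 were TWSG1, ATP6AP1, MAP3K6, MAEA and TRAK1, at 85.0, 83.0, 78.2, 76.3 and 73.4-fold lower in the same deposited table. Of these 15 folds, 11 were whole multiples of the 0.965 step and 3 were simple fractions of it, where 0.38% would be by chance. All 15 stayed lower on the step-adjusted scale.

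The 15 highest genes ranged from 26.3-fold to 94.4-fold in the authors' deposited table, and 10 of them were protein-coding, 3 pseudogenes and 2 long non-coding. ZBTB8OS (ENSG00000176261) was 94.4-fold higher in the deposited table. RFFL (ENSG00000092871), a ubiquitin ligase, was 47.1-fold and FBXO31 (ENSG00000103264), the substrate receptor of an SCF ubiquitin ligase, 41.3-fold higher in that deposited table. The deposited table listed the zinc finger gene ZNF215 at 32.9-fold, the histone gene HIST1H2AA at 31.2-fold, the spindle and kinetochore component SKA3 at 29.2-fold and FBXO30 at 26.6-fold higher. The olfactory receptor genes OR9Q2, OR10G7 and OR5L2 were 30.5, 27.2 and 26.3-fold higher in the deposited table. The long non-coding genes LINC00917 and ENSG00000260804 were 34.5 and 32.9-fold higher, and the pseudogenes ENSG00000232727, NANOGP2 and ENSG00000213630 were 39.6, 28.0 and 28.0-fold higher in the deposited table. Of these 15 folds, 6 were whole multiples of the 0.299 step and 6 were simple fractions of it. RFFL, at 157.5 steps, lay just outside the limit for a fraction. Pseudogenes, histone genes and olfactory receptors can share sequence with similar copies, which was not examined here, so their values are uncertain. Of all 229 listed genes with olfactory receptor symbols, a group chosen after the table was seen, 173 were higher in the deposited table.

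Most listed genes of ribosomes, reference sets, the cytoskeleton and the proteasome were lower in the treated library as deposited, while the medians of these lists were close to 0 on the step-adjusted scale. All 23 listed cytosolic ribosomal protein genes (of 30 in the list) were lower in the authors' deposited table, with a median of 2.84-fold. RPS15, RPS14 and RPL32 were 7.53, 5.51 and 4.32-fold lower in the deposited table. Of 15 listed housekeeping reference genes 13 were lower, with a median log2 fold of -1.64, and the deposited table listed EMC7 at 7.51-fold and REEP5 at 6.77-fold lower but TBP, the TATA-binding protein, at 4.80-fold higher. ACTB and GAPDH, named here after their values were seen, were 3.02 and 2.71-fold lower in the deposited table but turned to step-adjusted log2 values of 0.096 and 0.25. Ribosome biogenesis and MYC target genes were lower in 11 of 11 listed members, among them POLR1B at 8.69-fold and DKC1 at 5.45-fold lower in the deposited table. The step-adjusted medians were 0.19 for ribosomal proteins, 0.055 for reference genes and 0.0049 for ribosome biogenesis, all above 0. As deposited, these medians lay at percentiles 89.9, 68.2 and 64.1 of random lists, so they were less lowered than those of most random lists. Of the 14 listed tubulin, actin and regulator genes 13 were lower (median log2 -1.68, step-adjusted 0.0082), with the focal adhesion protein VCL at 36.7-fold lower and TUBB6 at 5.68-fold higher in the deposited table. The proteasome list was lower in 18 of 19 members (median log2 -1.87, step-adjusted -0.18 but 0.11 with unlisted members). Its subunits PSMB6 and PSMD1 were 9.04 and 8.48-fold lower and PSMA3 was 9.26-fold higher in the authors' deposited table.

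Listed energy metabolism genes were likewise mostly lower. Of 15 listed glycolysis genes 14 were lower in the authors' deposited table, with a median of 4.04-fold (step-adjusted log2 -0.32). PFKL, PKM and GPI, which encode glycolytic enzymes, were 8.17, 7.65 and 7.57-fold lower in the deposited table. All 18 listed nuclear genes of oxidative phosphorylation were lower, with a median of 4.14-fold (step-adjusted log2 -0.36 but 0.050 with unlisted members). The complex II subunit SDHC was 14.5-fold lower in that deposited table. Hypoxia response genes were lower in 14 of 16 listed members (median 4.40-fold, step-adjusted log2 -0.45). The angiopoietin-like gene ANGPTL4 was 28.96-fold and the carbonic anhydrase CA9 13.5-fold lower in the deposited table, while the mitophagy receptor BNIP3 was 7.47-fold higher.

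Listed genes of the lysosome, the secretory pathway and lipid synthesis were mostly lower in the treated library. All 18 listed lysosome and TFEB target genes (of 24) were lower in the authors' deposited table, with a median of 7.40-fold. That median lay at the 0.27 percentile of 10000 random lists of the same size drawn from the listed genes, and its step-adjusted log2 value was -1.20. The proton pump subunits ATP6V1H and ATP6V1A were 13.5 and 10.6-fold lower and the cholesterol carrier NPC2 12.7-fold lower in the deposited table. Of the autophagy genes 14 of 14 listed were lower (median 3.43-fold, percentile 57.0, step-adjusted log2 -0.087 but 0.26 with unlisted members, above 0 when recentred on all listed genes), with WIPI1 at 13.5-fold and ULK1 at 6.23-fold lower in the deposited table. Endocytosis genes were lower in 14 of 15 listed members (median log2 -1.45, step-adjusted 0.24), and the clathrin adaptor subunit AP2M1 was 6.06-fold lower in the deposited table. All 16 listed endoplasmic reticulum chaperone genes and XBP1 or ATF6 targets were lower, with a median of 4.70-fold (percentile 15.4, step-adjusted log2 -0.54). CRELD2, DNAJB9 and HYOU1, which act in protein folding in the endoplasmic reticulum, were 45.4, 25.1 and 13.6-fold lower in the deposited table. Cholesterol synthesis genes were lower in 11 of 12 listed members (median 4.67-fold, step-adjusted log2 -0.53 but 0.69 or more with unlisted members), with MSMO1 at 43.4-fold and HSD17B7 at 41.5-fold lower in the deposited table. Fatty acid synthesis genes were lower in 9 of 10 (median 3.50-fold, step-adjusted log2 -0.12 but 0.20 with unlisted members, above 0 when recentred on all listed genes), and the regulator SREBF1 and the desaturase SCD were 24.1 and 17.6-fold lower in the deposited table.

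The NF-kB list had the lowest median of the 38 lists, followed by the lysosome list and the matrix list. Of 12 listed NF-kB targets and cytokines (of 25) 11 were lower in the authors' deposited table, with a median of 10.6-fold, at the 0.01 percentile of random lists and -1.71 on the step-adjusted log2 scale. The apoptosis inhibitor BIRC3 was 33.8-fold, the interleukins IL1B and IL1A 23.4 and 14.5-fold and the colony-stimulating factor CSF3 16.4-fold lower in the deposited table. Interferon response genes were lower in 11 of 13 (median 6.19-fold, percentile 4.43, step-adjusted log2 -0.94 but 0.69 or more with unlisted members), with HERC5 at 19.3-fold, RSAD2 at 18.3-fold and ISG15 at 9.61-fold lower in the deposited table. Extracellular matrix and protease genes were lower in 16 of 18 listed members (of 28), with a median of 7.27-fold at the 0.26 percentile and a step-adjusted log2 value of -1.17. The laminin chain LAMA3 was 49.2-fold, the collagenase MMP1 23.7-fold and the membrane protease MMP14 19.5-fold lower in the deposited table. These 3 lists (lysosome, NF-kB and matrix) were the only ones of 38 with a median outside the central 95% of random lists, where 1.9 would be by chance. Folds at whole multiples of the step were found for 4 of 18 lysosome, 6 of 12 NF-kB and 4 of 18 matrix genes. Where unlisted members were given any value under 2-fold, the lysosome median log2 was -2.51 and the matrix median -1.36, but the NF-kB median could lie anywhere from -1.0 to 1.0. On the step-adjusted scale the same medians were -0.81 for the lysosome, 0.33 for the matrix and 0.69 or more for NF-kB. Only the lysosome list of these 3 thus stayed below 0. On that scale unlisted members lie at 0.69 or above by design. The NF-kB list has more unlisted than listed members, so its value is fixed by this and says nothing about its listed genes.

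**Figure D3:**
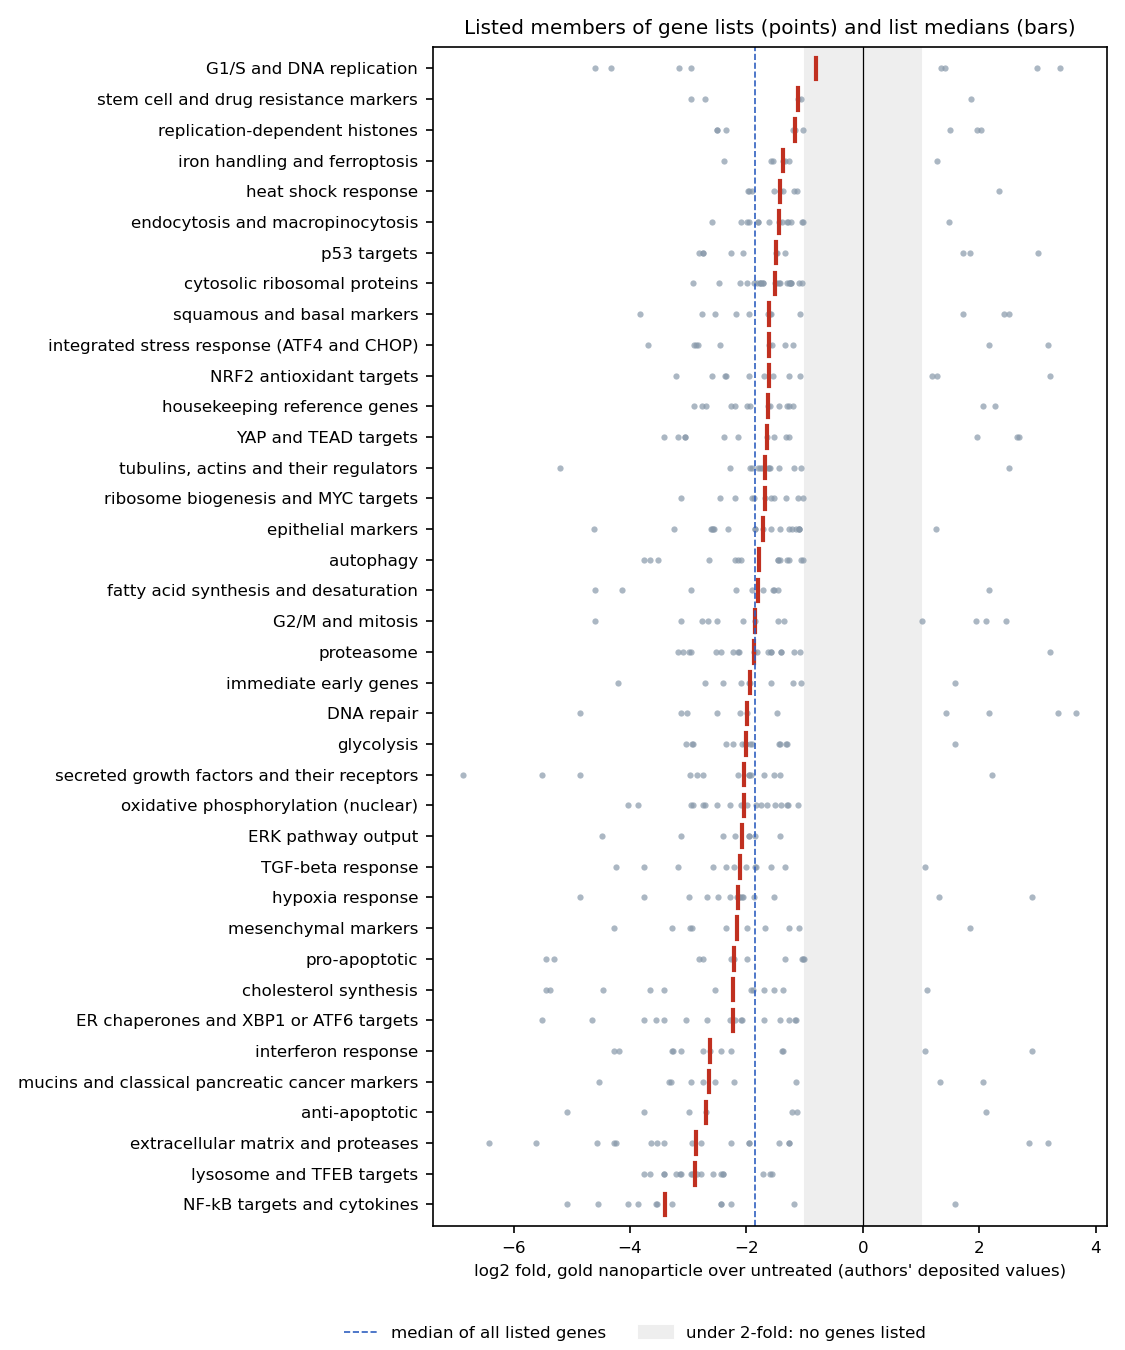
Deposited log2 folds (x axis, gold nanoparticle over untreated) of the listed members of the 38 gene lists with at least 5 listed members, 1 point per gene, with the list median as a bar, the median of all listed genes (-1.86) as a dashed line and the unlisted range as a grey band. All 38 medians lie below 0 as deposited (23 on the step-adjusted scale), and the NF-kB, lysosome and matrix lists have the lowest.

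Listed growth factor and signalling genes were mostly lower as deposited. Of 14 listed secreted growth factors and receptors 13 were lower in the authors' deposited table (median 4.13-fold, percentile 29.4, step-adjusted log2 -0.36 but 0.69 or more with unlisted members). Besides HBEGF, the vasoconstrictor peptide EDN1 was 45.4-fold and VEGFB 7.84-fold lower in the deposited table. VEGFA and EGFR, named after their values were seen, were 4.43 and 2.88-fold lower in the deposited table, and EGFR turned to a step-adjusted log2 value of 0.16. Genes of ERK pathway output were lower in 8 of 8 listed members (median 4.21-fold, step-adjusted log2 -0.38 but 0.48 or more with unlisted members), with the feedback inhibitor SPRY2 at 22.3-fold lower in the deposited table. Immediate early genes were lower in 9 of 10 (median 3.85-fold, step-adjusted log2 -0.25 but 0.69 or more with unlisted members), with FOSB at 18.4-fold lower in the deposited table. YAP and TEAD targets were lower in 10 of 13 (median log2 -1.65, step-adjusted 0.042), with AJUBA at 10.6-fold lower in the deposited table. TGF-beta response genes were lower in 11 of 12 (median 4.34-fold, step-adjusted log2 -0.42 but 0.23 with unlisted members), with the collagen chain COL1A1 at 18.8-fold lower in the deposited table.

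Cell cycle, DNA repair and p53 target genes went in both directions. At 72.7% lower, however, the p53 targets were close to the 77.4% of all listed genes. The folds of MCM7, POLA1, CCNB2, CCNA2, LIG1, PARP1, FDXR and CFLAR lay on a step or fraction, so their size is uncertain. Of 8 listed G1/S and replication genes 4 were lower and 4 higher in the authors' deposited table. The helicase subunit MCM7 and the transcription factor E2F1 were 24.1 and 20.04-fold lower, and the polymerase subunit POLA1 was 10.5-fold higher in the deposited table. Mitosis genes were lower in 9 of 13 listed members (median log2 -1.86, step-adjusted -0.17 but 0.69 or more with unlisted members), with the cyclins CCNB2 and CCNA2 at 24.1 and 8.69-fold lower in the deposited table. DNA repair genes were lower in 7 of 11 (median log2 -1.99, step-adjusted -0.30 but 0.69 or more with unlisted members). The DNA ligase LIG1 was 28.96-fold lower, while PARP1, which acts in break repair, was 12.7-fold higher in the deposited table. The p53 targets were lower in 8 of 11 (median log2 -1.50, step-adjusted 0.19), with GADD45A at 6.74-fold lower and FDXR at 8.07-fold higher in the deposited table. Genes of the histone list, which holds replication-dependent histones and the replication-independent linker histone gene H1F0 (5.66-fold lower in the deposited table), were lower in 6 of 9 (median log2 -1.16, step-adjusted 0.53), with HIST1H2BK at 5.68-fold lower and HIST1H4H at 4.09-fold higher in the deposited table. All 11 listed pro-apoptotic genes were lower (median 4.63-fold, step-adjusted log2 -0.52 but 0.67 with unlisted members), with BAK1 at 39.4-fold lower in the deposited table. Of 7 listed anti-apoptotic genes 6 were lower (median 6.46-fold, also lower on the step-adjusted scale but 0.52 with unlisted members), with CFLAR at 13.5-fold and XIAP at 6.46-fold lower in the deposited table.

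Stress response genes that were listed were mostly lower as deposited, while the medians of their lists lay slightly above 0 on the step-adjusted scale. Of the metallothioneins only 3 of 10 were listed in the authors' deposited table. MT1E and MT3 were 2.99 and 2.39-fold higher and MT2A 2.19-fold lower in the deposited table. Both higher folds were whole steps, at 10 and 8 treated steps, so their size is uncertain. MT2A turned higher on the step-adjusted scale, at a log2 value of 0.56. Heat shock genes were lower in 8 of 9 listed members (median log2 -1.42, step-adjusted 0.27), with HSPB1 and DNAJA1 at 3.93 and 3.87-fold lower and the small heat shock protein CRYAB at 5.08-fold higher in the deposited table. NRF2 antioxidant targets were lower in 9 of 12 (median log2 -1.62, step-adjusted 0.073), with AKR1C2 and SRXN1 at 9.23 and 5.18-fold lower and ME1 at 9.27-fold higher in the deposited table. Integrated stress response genes were lower in 9 of 11 (median log2 -1.61, step-adjusted 0.080), with the amino acid transporter subunit SLC3A2 at 7.44-fold lower and the serine synthesis enzyme PHGDH at 9.08-fold higher in the deposited table. Iron handling and ferroptosis genes were lower in 6 of 7 (median log2 -1.36, step-adjusted 0.33), with the iron transporter SLC11A2 at 5.25-fold lower in the deposited table.

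Listed markers of epithelial, mesenchymal, squamous and classical identity were mostly lower as deposited, with step-adjusted medians on both sides of 0. Epithelial markers were lower in 18 of 19 listed members in the authors' deposited table (median log2 -1.72, step-adjusted -0.029 but 0.19 with unlisted members, above 0 when recentred on all listed genes), with the keratins KRT8 and KRT19 at 24.5 and 6.07-fold and the tight junction protein OCLN at 9.46-fold lower in the deposited table. Mesenchymal markers were lower in 9 of 10 (median log2 -2.17, step-adjusted -0.48 but 0.69 or more with unlisted members), with SNAI1, SNAI2 and FN1 at 9.69, 7.80 and 7.67-fold lower in the deposited table. Mucins and classical pancreatic cancer markers were lower in 8 of 10 (median 6.22-fold, percentile 5.31, step-adjusted log2 -0.95 but 0.69 or more with unlisted members), with TFF2, AGR2 and MUC4 at 23.2, 10.1 and 7.72-fold lower in the deposited table. Squamous markers were lower in 9 of 12 (median log2 -1.61, step-adjusted 0.082), with KRT16 at 14.2-fold lower and SPRR3 at 5.68-fold higher in the deposited table. Stem cell and drug resistance markers were lower in 4 of 5 (median log2 -1.11, step-adjusted 0.58), with the transporter ABCC1 at 7.72-fold lower in the deposited table. Of 4 listed nucleoside transport and metabolism genes 3 were lower, among them SLC29A1, the equilibrative transporter that carries gemcitabine, at 11.6-fold lower in the deposited table. The other lower genes, NT5C and DCTD, turned to step-adjusted log2 values of 0.21 and 0.38. Markers of other cell types were rarely listed. The deposited table held 2 of 14 fibroblast markers, both lower, though ACTA2 turned to a step-adjusted log2 value of 0.59. It held 3 of 16 immune markers (CD14 and CD68 at 3.88 and 3.80-fold lower, CD79A at 2.39-fold higher). It also held 1 of 10 endothelial markers (TIE1 at 2.09-fold higher) and 0 of 14 acinar and islet markers.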

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

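Recentring by the ratio of the step sizes, leaving out genes on a step or fraction, matching random lists on the steps, and giving unlisted members a log2 value of -1 or 1 were chosen after seeing the data. At 3-fold 1187 genes were higher and 4793 lower. Without genes on a step or fraction 694 were higher and 4566 lower, and of 37 lists 36 had a median below 0, the exception being G1/S and DNA replication (1.35). Recentring on the median of the listed genes left 1853 genes at least 2-fold lower and 20 of 38 list medians below 0. Recentring by the step ratio left 2189 and 23. Setting the median of the listed genes to 0 makes an even split of genes by design, so the first of these results does not test the scaling. With unlisted members at -1 all 38 list medians lay below 0, and with these at 1, 19 did. With the step ratio then taken out, 4 lists lay below 0 in either case (lysosome, hypoxia, endoplasmic reticulum chaperones and glycolysis), though some unlisted members may not have been measured. Every unlisted member then lies above 0 by design, so the count of 4 depends on how many members of each list are unlisted. Since unlisted genes are not part of either recentring, the higher side is then only a minimum. The list medians that turned positive are given as log2 values on the median-recentred and then the step-adjusted scale: heat shock 0.44 and 0.27, NRF2 targets 0.24 and 0.073, integrated stress response 0.25 and 0.080, p53 targets 0.36 and 0.19, G1/S and DNA replication 1.06 and 0.89, iron handling 0.50 and 0.33, YAP and TEAD targets 0.21 and 0.042, squamous markers 0.25 and 0.082, stem cell markers 0.75 and 0.58, ribosome biogenesis 0.17 and 0.0049, ribosomal proteins 0.36 and 0.19, endocytosis 0.41 and 0.24, tubulins and actins 0.18 and 0.0082, histones 0.70 and 0.53, and reference genes 0.22 and 0.055. Fatty acid synthesis (0.055), autophagy (0.083) and epithelial markers (0.14) turned positive only on the median-recentred scale. Of 185 genes that the naming rule picked, 8 turned positive on both scales, namely MT2A (0.73 and 0.56), SLC39A14 (0.28 and 0.11), FTH1 (0.32 and 0.15), ACSL4 (0.50 and 0.33), SOX9 (0.75 and 0.58), NT5C (0.38 and 0.21), DCTD (0.55 and 0.38) and ACTA2 (0.76 and 0.59). Of the 4 genes named after their values were seen, EGFR (0.33 and 0.16), ACTB (0.27 and 0.096) and GAPDH (0.42 and 0.25) turned positive and VEGFA did not. These sign changes follow from adding a constant to every fold. The mean in place of the median left all 38 lists below 0, and matching random lists on the steps left 3 lists outside the central 95%. Lower or no expression minimums, other pseudocounts, equal totals, upper-quartile scaling, a 1.5-fold threshold and expression-matched random lists were not run, because the values analysed are folds of at least 2. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out.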

Other observations

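All tests below were chosen after the result was seen, except the comparison of single-coding-exon genes. Of 724 gene ontology terms with at least 20 listed genes in the authors' deposited table, 5 had more than 50% of their genes higher, all of them terms of olfaction or of G protein-coupled receptors. Olfactory receptor activity, the set of odorant receptors of the nasal epithelium, had 162 of 214 listed genes higher, with a median of 3.89-fold. Once olfactory receptors were left out, genes of G protein-coupled receptor signalling were higher in 41 of 142. Keratin filament genes, many of them hair keratin-associated proteins, were higher in 21 of 42. The next term by share was potassium ion transport (42.3% of 26 listed genes higher). After it came the condensed chromosome kinetochore (40% of 35), chromatin organisation (40% of 20) and the centromeric region (37.5% of 32). Nucleosome assembly genes, mainly histones, were higher in 22 of 65, with a median log2 fold of -1.36 that became 0.33 on the step-adjusted scale. Of the sets that were mostly lower, translational elongation had 60 of 60 listed genes lower (median 2.92-fold, percentile 92.6 of random lists) and mRNA metabolic process 147 of 149 (median 3.40-fold, percentile 71.5), so both medians were less lowered than those of most random lists. The electron transport chain had 56 of 58 lower (median 4.04-fold, percentile 16.2) and the Golgi membrane 175 of 200 (median 4.01-fold, percentile 3.39). The step-adjusted medians of these 4 sets were 0.15, -0.075, -0.32 and -0.31, so translational elongation was not lower on that scale. All these sets were picked from the 724 terms after their shares were seen, so neither shares nor percentiles are evidence that a set stands apart.

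The lower level of ribosomal protein and reference genes in the treated library may follow from the scaling between the libraries. If 1 step is what 1 read is worth, a read counted 3.23 times less in the treated library than in the untreated one. Correct scaling of a deeper treated library would also give such a ratio, so the ratio does not show that the scaling was wrong. With that ratio taken out, the median log2 fold of the ribosomal protein genes moved from -1.50 to 0.19. How close to 0 it should come was set only after both values were known, so that value does not decide, and scaling cannot be told apart from an effect of the gold nanoparticle on abundant transcripts with 1 library per group.

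For the higher olfactory receptor genes, reads shared between paralogs stay open, as 21.8% of the 133 of them on a step or fraction lay on a fraction (95% Wilson interval 15.6% to 29.6%), but reads given whole to 1 copy would leave whole steps and 40 further genes lay on neither. A deeper treated library alone cannot be told apart from other causes. Of these genes 33 had 32 or more whole steps, where an equal background on the deposited scale would give about 9.91 untreated reads. With PCR copies at 3.31 reads per molecule, however, such a gene would have a chance of 0.05 of no untreated molecule. Reads from genomic DNA or unspliced RNA in the treated library remain a candidate explanation. Leaving out olfactory receptors, 17.0% of 658 higher protein-coding genes on a whole step had a single coding exon, against 4.44% of 1485 lower ones. The difference was 12.6 percentage points (95% interval 9.65 to 15.8, with genes taken as independent). Single-exon genes are also often little expressed, which that test does not separate, and an effect of the treatment stays open as untested.

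The third pattern is that 14 of the 15 largest decreases lay on a step or fraction, which may come from values under 1 being raised to 1 before the folds were taken, so that such folds would rest on 3 treated reads or fewer and be set by the untreated library alone. Counting error cannot be told apart. On the deposited scale the 98 lower genes with 32 or more whole untreated steps would have 103 or more treated reads at an equal level. At 34.5 reads per molecule, however, a gene with 32 such steps would have a chance of 0.05 of no treated molecule. The largest decreases, such as TRAK1 at 76 and DAAM1 at 136 steps, would need more reads per molecule. Without that scaling, 32 untreated reads would match 32 treated reads, and fewer reads per molecule would be enough. Uneven amplification or loss of molecules from 10 ng of RNA cannot be told apart from an effect of the treatment without a second library. Outside the olfactory receptors 137 genes showed the opposite, with 32 or more whole treated steps. A treated step is 0.299 wide and an untreated step 0.965, so 32 treated steps are a much smaller fold than 32 untreated steps. The counts of 137 and 98 are therefore not comparable.

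Among the symbols as deposited, 14 stand as 5-digit spreadsheet dates, all of genes lower in the treated library, and by identifier 12 of these 14 are MARCH or SEPT family genes.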
